A study of Mus musculus with 14 samples.

How the data were processed

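Total RNA from whole lungs of C3H/HeJ mice was measured on Affymetrix expression arrays. C3H/HeJ is an inbred strain that carries a defective Toll-like receptor 4 and does not respond to lipopolysaccharide. Per the labels, 14 arrays fall into 2 groups, 7 from mice given flagellin (1 µg, by the nose) and 7 from mice given PBS, with lungs taken at 1 h. Each sample is labelled as a mouse with a replicate number from 1 to 7, and no label names a cage, day, sex or array batch. Groups were taken from the labels alone, and arrays are named by their labelled group and replicate number.

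The deposited values are log2 signals per probe set. Per the submitters' processing notes, GCOS, RMA and affy were used, with no versions given. RMA subtracts background, quantile-normalises the arrays and combines the probes of a set into 1 log2 value. The deposited log2 values have nearly the same quartiles on all arrays, with medians between 6.52 and 6.55, lower quartiles between 6.19 and 6.22 and upper quartiles between 7.40 and 7.48. Highest signals lay between 13.7 and 14.5. Detection calls were not used here, and differences of genes with signals near the lower quartile are compressed, since background keeps the signal from falling further. A difference in total RNA between lungs cannot be seen after quantile normalisation. All columns had a sample, and the number of arrays limits the precision.

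Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here. Gene numbers of 34741 probe sets matched the RefSeq gene table, and this changed 0 symbols. No genome build is given in the sources used here, so no coordinates are printed. Each gene was represented by the probe set with 1 symbol and the highest mean over all 14 arrays, which gave 18193 genes. No filter on dim genes was applied.

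Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings), arrays labelled flagellin minus arrays labelled PBS, with Benjamini-Hochberg adjustment over all 18193 genes and a threshold of 0.05. A gene was called at least 2-fold changed with a log2 difference of 1 or more in size. An adjusted p of a gene comes from this limma model over all 14 arrays unless another fit, another adjustment or other arrays are named with it. Gene lists were tested with limma's camera with its preset inter-gene correlation of 0.01, adjusted over 28 lists, and again with a correlation estimated for each list and with fry. Camera compares a list with all other genes, and fry asks whether the list's genes move, on balance, one way. RNA quality was read from the 3-prime minus 5-prime signal of the Affymetrix GAPDH and beta-actin controls and compared with an exact two-sided permutation test over 3432 arrangements.

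The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The 12 response lists are chemokines, inflammatory cytokines and growth factors, NF-kappaB subunits and feedback regulators, immediate early genes, antimicrobial and acute phase products, type I interferon response, Toll-like receptors and adaptors, endothelial adhesion, coagulation and prostanoid genes, glucocorticoid and stress targets, circadian clock genes, heat shock genes and cell cycle genes. The 16 cell type lists hold markers of neutrophils, monocytes and interstitial macrophages, alveolar macrophages, alveolar type II and type I cells, club cells, ciliated cells, endothelium, fibroblasts, smooth muscle, B cells, T and NK cells, thymocytes, cardiac muscle, adipocytes and red blood cells. Of 600 list entries, 553 matched a measured gene. The rule asks for the 14 largest rises and the 8 largest falls among genes past the threshold, but only 1 gene past it was higher, B3gat1, so 1 rise is named. It further takes the 3 members with the smallest p of each response list, the 2 of each cell type list, and Tlr5 and Tlr4. That gave 70 genes, and 23 more were chosen after their values were seen. Of the 93 genes, 37 had several probe sets, all of which went in one direction for 28. Of the 7 called ones with several probe sets, this held for 6.

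Alternatives tried were the replicate number as a block, median centring, a second quantile normalisation, leaving out the dimmest 40% of genes, averaging the probe sets of a gene, leaving out cross-hybridising probe sets, array weights, trended and robust variance, the GAPDH control difference as a covariate, probe sets in place of genes, a threshold of 0.01 and leaving out each array in turn. Added after seeing the data were a block for 2 sets of arrays split at the widest gap of the clock gene Dbp, the comparison within each set, that block or the GAPDH covariate with array flagellin 7 left out, robust regression, and the estimated correlation in the settings where a list reversed.

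The gene test was checked on simulated data with the means and spread of these 18193 genes and 7 arrays per group. With 100 genes changed by a log2 value of 0.5 and 100 by 1, it recovered 98% and 100%, with 12 false calls. With 6 of the 7 arrays carrying the change it recovered 93% and 96%, with 9 false calls. Noise was drawn for each gene on its own, and the seventh array stayed at the unchanged level. These rates do not carry over to the 14 arrays here. There 8 genes were called at least 2-fold lower, against 16 without array flagellin 7. In the camera check, the 1 shifted list was called, and 0 of 25 lists sharing no gene with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.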

Results

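Gene expression was measured in the lungs of 14 C3H/HeJ mice, 7 labelled as given flagellin and 7 labelled as given PBS, 1 h before. Flagellin, the protein of the bacterial flagellum, is sensed outside the cell by Toll-like receptor 5, and the strain's defect in Toll-like receptor 4 keeps traces of lipopolysaccharide from acting. The comparison asks which lung genes change within 1 h of flagellin. The values are log2 RMA signals, and the 14 arrays have nearly the same distribution, with medians between 6.52 and 6.55.

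The neutrophil-attracting chemokines Cxcl1 and Cxcl2 were lower in the arrays labelled flagellin than in those labelled PBS. Cxcl1 had a log2 signal of 8.06 ± 1.82 (SD, n = 7) in the arrays labelled flagellin and 11.38 ± 0.34 (n = 7) in those labelled PBS, a 9.97-fold lower level (adjusted p = 0.0332). The size depends on the probe set, since the other 2 of Cxcl1, both of lower signal, had log2 differences of -3.35 and -1.17, against -3.32 here, and the last was not called (adjusted p over all probe sets 0.0988). Cxcl2 stood at 7.52 ± 1.53 and 10.28 ± 0.34, 6.78-fold lower (adjusted p = 0.0332). Without the array labelled flagellin 7, which stood apart from its group, Cxcl1 was 15.9-fold and Cxcl2 10.1-fold lower in the other 6. The NF-kappaB regulators Nfkbiz and Tnfaip3, the cytokine Tnf, and the early genes Egr1, Zfp36 and Ier2 were lower as well, each at least 2-fold. In background knowledge flagellin raises such genes, so the direction in the arrays as labelled is the opposite of its known effect. The groups are therefore called "labelled flagellin" and "labelled PBS" throughout, and every direction rests on these labels.

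Over all 14 arrays, limma called 44 genes lower and 1 higher in the arrays labelled flagellin, with 8 lower and 0 higher at least 2-fold. At an unadjusted p under 0.05, 2126 genes differed, of which 0 were at least 2-fold higher. The median log2 difference of the 44 lower genes was -0.39. The smallest adjusted p was 0.0113. The higher gene was B3gat1, a glucuronyltransferase, at 6.39 ± 0.05 against 6.23 ± 0.06 (n = 7 each, adjusted p = 0.0403), near the low end of the signal range. This rests on 1 of 4 probe sets of B3gat1, the other 3 having log2 differences of 0.06, 0.02 and -0.02 (adjusted p over all probe sets 0.482, 0.877 and 0.902). With the arrays quantile-normalised again, 5 genes were higher and 19 lower.

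The array labelled flagellin 7 did not follow the other 6 arrays of its group. Its Cxcl1 signal was 12.12, above the PBS range of 10.96 to 11.85, while the other 6 lay between 7.09 and 8.04. It was above all other arrays labelled flagellin for 33 of the 44 lower genes, and within or above the PBS range for 27. For 38 of the 44 genes, every array labelled PBS was above all 6 other arrays labelled flagellin. The 44 were picked for a difference on these same arrays, so this separation is partly built in and is no independent support. Leaving out each array in turn was planned, but this array is singled out after its values were seen. Taking out an array that goes against the difference tends to raise the counts. Without it, 268 genes were lower and 16 higher, with 16 lower and 0 higher at least 2-fold. These included all 44 lower genes and all 8 of the 2-fold ones. Without PBS 6, 81 were lower and 3 higher. Without any 1 of the other 12 arrays, 6 to 12 were lower, all of them among the 44, and all 44 kept a negative difference. These fits share most arrays with the one that picked the 44, so the kept sign is no independent support.

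**Figure D1:**
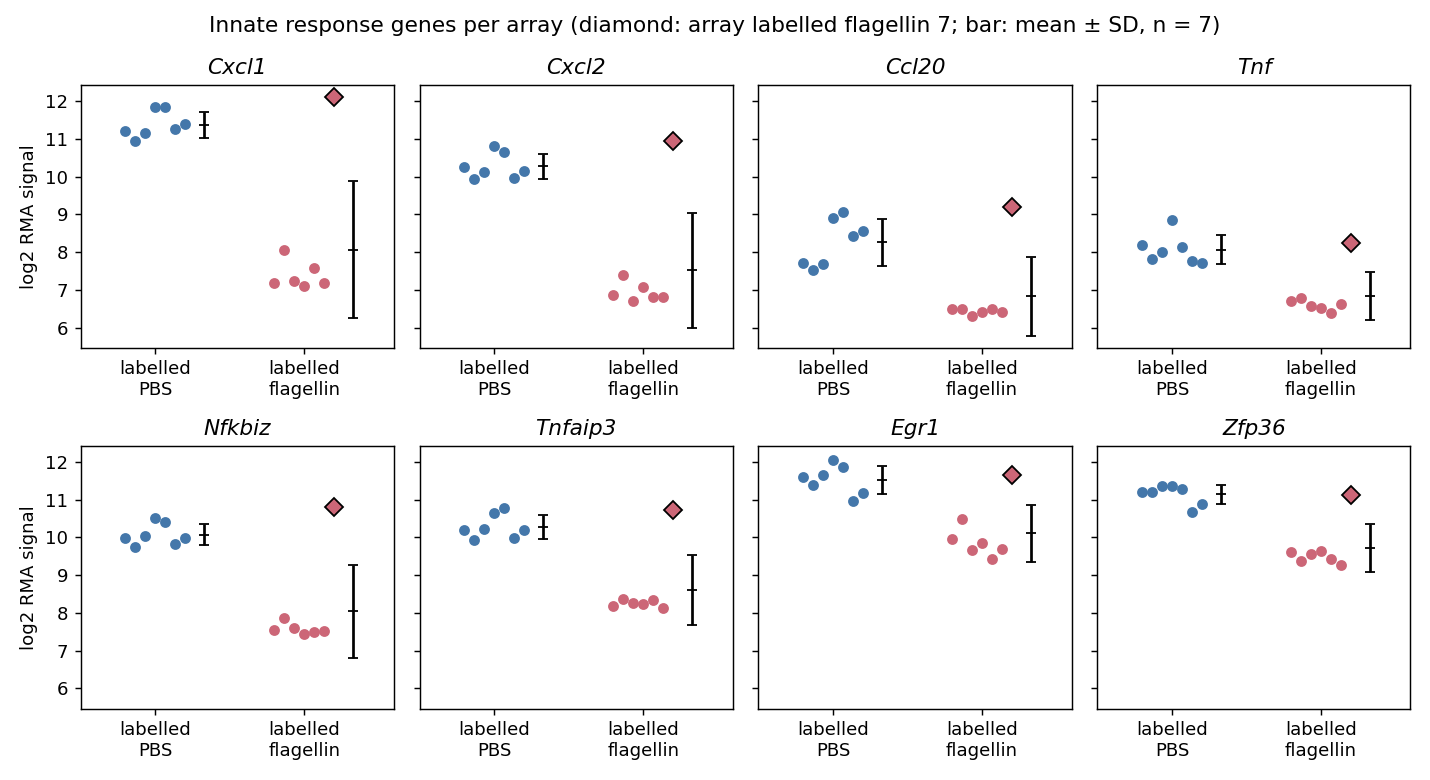
Log2 RMA signal of 8 genes in each array, by labelled group, with the mean and SD of 7 arrays as a bar beside each group. The array labelled flagellin 7 is drawn as a diamond. For Cxcl1 it stands at 12.12, while the other 6 arrays of its group lie between 7.09 and 8.04 and the 7 labelled PBS between 10.96 and 11.85.

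The 14 arrays also fell into 2 sets by the clock gene Dbp, a transcription factor with a strong daily rhythm that was chosen after its values were seen. Dbp was 9.36 or more in 3 arrays of each group and 7.56 or less in the other 4 of each. Within the arrays of high Dbp, 148 genes were lower and 5 higher, and the median log2 difference of the 44 genes was -0.41. Within the arrays of low Dbp, which hold flagellin 7, limma called 0 genes (1094 at an unadjusted p under 0.05), and the median was -0.32. All 44 had a negative difference in both sets, but they were picked on these same 14 arrays, so this is no independent support. The Cxcl1 difference was -3.95 in the first and -2.84 in the second. With the set as a block, 113 genes were lower and 6 higher.

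**Figure D2:**
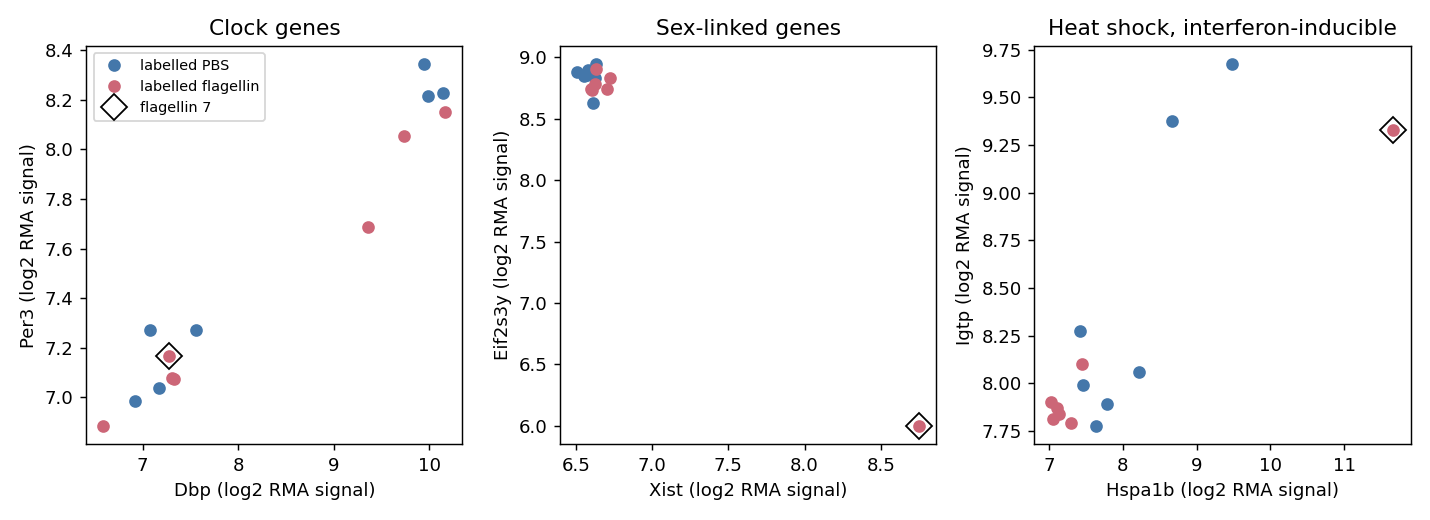
Log2 RMA signals of pairs of genes, each point 1 array, coloured by labelled group, with flagellin 7 marked by a diamond. All 6 genes were chosen after their values were seen. Dbp against Per3 shows 6 arrays with Dbp of 9.36 or more and 8 with 7.56 or less, in both groups. Xist against Eif2s3y sets flagellin 7, with Xist at 8.75, apart from the other 13. Hspa1b against Igtp shows PBS 6, PBS 7 and flagellin 7 with the 3 highest Igtp signals, 9.38, 9.68 and 9.33.

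Of 25 measured chemokines 3 fell, 6 when adjusted over the list alone. They were Cxcl1, Cxcl2 and Ccl17, a T cell attractant (log2 difference -0.28, adjusted p = 0.0400). Camera called the list lower (adjusted p = 3.9e-04), but with an estimated correlation the adjusted p was 0.362. Without flagellin 7, 9 members fell, 12 adjusted over the list alone. Among them, chosen after their values were seen, were Ccl20, an attractant of dendritic cells and lymphocytes made by epithelium, with a log2 difference of -1.84 (-1.44 over all 14 arrays, adjusted p = 0.120), and Ccl3, at -0.86 (-0.67 over all 14, adjusted p = 0.181).

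Of 25 NF-kappaB subunits and feedback regulators 3 fell, and 10 when adjusted over the list alone. Nfkbiz, an inducible co-regulator of NF-kappaB, fell by 2.03 on the log2 scale, from 10.07 ± 0.28 to 8.04 ± 1.23 (n = 7 each, adjusted p = 0.0400). Its other 2 probe sets, of lower signal, had differences of -1.64 and -0.52 and were not called (adjusted p over all probe sets 0.0591 and 0.184). Tnfaip3, the A20 protein that ends NF-kappaB signalling, fell by 1.67 (adjusted p = 0.0394). Nfkbia, the inhibitor IkappaB-alpha, fell by 0.50 (adjusted p = 0.0400), with the 7 arrays labelled PBS between 12.88 and 12.94. The other 4 probe sets of Nfkbia, all of lower signal, had differences of -1.08, -0.95, -0.76 and -0.30, so its size depends on the probe set. Camera gave an adjusted p of 6.5e-08, against an adjusted p of 0.362 with an estimated correlation. Without flagellin 7, 10 members fell, 16 adjusted over the list alone, and the differences of Nfkbiz, Tnfaip3 and Nfkbia were -2.50, -2.02 and -0.60.

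Immediate early genes, which are transcribed within minutes of a stimulus, had the most members past the threshold. Of 40 members 9 fell, and 25 when adjusted over the list alone. Egr1 and Zfp36, the latter a protein that destabilises cytokine mRNA, both fell by 1.42 (adjusted p = 0.0394 and 0.0131). Ier2 fell by 1.17 (adjusted p = 0.0275), and Dusp1, a phosphatase of MAP kinases, by 0.70 (adjusted p = 0.0321). Camera gave an adjusted p of 1.5e-20, and with an estimated correlation the adjusted p was 0.362. Without flagellin 7, 25 members fell, 29 adjusted over the list alone. Atf3, Junb and Fos, chosen after their values were seen, had differences of -1.93, -1.48 and -1.32 then, and of -1.53, -1.21 and -1.11 over all 14 arrays (adjusted p = 0.0748, 0.0609 and 0.0512).

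Of 25 inflammatory cytokines and growth factors, 1 fell, and 7 when adjusted over the list alone. It was Tnf, from 8.07 ± 0.39 to 6.84 ± 0.64 (n = 7 each, log2 difference -1.23, adjusted p = 0.0400). Il1a differed by -0.64 (adjusted p = 0.154) and Osm by -0.20 (adjusted p = 0.189). The list had a camera adjusted p of 0.00152, and an adjusted p of 0.362 with an estimated correlation. Without flagellin 7, 8 members fell, 12 adjusted over the list alone, among them Il1a at -0.83 and, chosen after their values were seen, Il1b at -0.83 and Csf2 at -0.75. Over all 14 arrays Il1b stood at -0.64 (adjusted p = 0.247) and Csf2 at -0.55 (adjusted p = 0.285). The transcription factor Irf1, also chosen later and in none of the lists, was at -1.05 over all 14 arrays (adjusted p = 0.0587) and fell by 1.30 without flagellin 7.

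Of 25 glucocorticoid and stress targets, 2 fell, Errfi1 and Cebpd, and 7 fell and 1 rose when adjusted over the list alone. Errfi1, an inhibitor of the EGF receptor, fell by 0.73 (adjusted p = 0.0113), and Cebpd by 0.39 (adjusted p = 0.0472), while a dim second probe set of Cebpd stood at -0.05 (adjusted p over all probe sets 0.555). Mt2 stood at -0.36 (adjusted p = 0.0751). Without flagellin 7, 6 members fell, Mt2 by 0.37 among them, and 10 fell and 1 rose when adjusted over the list alone. Over all 14 arrays the camera adjusted p was 1.4e-04, and with an estimated correlation the adjusted p was 0.362. Of 26 endothelial adhesion, coagulation and prostanoid genes, 0 passed over all genes tested and 3 fell when adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, stood at -1.21 (adjusted p = 0.0791), the coagulation trigger F3 at -0.43 (adjusted p = 0.110) and Adamts1 at -0.32 (adjusted p = 0.0861). Without flagellin 7, 4 members fell, including these, with Ptgs2 at -1.54. The list's camera adjusted p was 0.0332 over all 14 arrays, against an adjusted p of 0.362 with an estimated correlation.

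The flagellin receptor Tlr5 had a signal of 6.88 ± 0.05 in the arrays labelled flagellin and 6.87 ± 0.03 in those labelled PBS (n = 7 each, log2 difference 0.00, adjusted p = 0.986). The signal of this probe set is near the low end of the range, which limits what can be seen with it. Tlr4 differed by -0.07 (adjusted p = 0.571). Of 28 Toll-like receptors and adaptors, 0 passed over all genes tested and 3 fell when adjusted over the list alone. The lipoprotein receptor Tlr2 stood at -0.38 (adjusted p = 0.0609), Cd14 at -0.41 (adjusted p = 0.101) and Tab2 at -0.11 (adjusted p = 0.193). Without flagellin 7, 2 members fell, Tlr2 by 0.47 and Cd14 by 0.50. Over all 14 arrays the camera adjusted p of the list was 0.0199, and with an estimated correlation the adjusted p was 0.362.

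Heat shock genes depended on 1 array. Of 17 members 0 passed over all 14 arrays, and the camera adjusted p was 0.723, with a mean log2 difference of -0.06, a median of 0.01 and a camera direction upwards. Dnajb1, a co-chaperone, stood at -0.55 (adjusted p = 0.393), Hspa8 at -0.20 (adjusted p = 0.653) and Hspb8 at -0.15 (adjusted p = 0.321). Dnajb1 was 10.90 in flagellin 7, between 8.76 and 8.90 in the other 6 arrays of that group, and between 9.53 and 9.97 in those labelled PBS. Without flagellin 7, 6 of the 17 fell, 10 adjusted over the list alone, with Dnajb1 at -0.84, Hspa8 at -0.37 and Hspb8 at -0.21.

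In 4 further response lists 0 members passed over all genes tested, and camera did not call the list. The antimicrobial and acute phase products had an adjusted p of 0.442, with the airway protein Bpifa1 at -0.46 (adjusted p = 0.199), Muc5b at -0.22 (adjusted p = 0.343) and the siderophore-binding Lcn2 at -0.21 (adjusted p = 0.229). Without flagellin 7, Lcn2 fell by 0.27. The type I interferon response had an adjusted p of 0.991, with Oasl1 at 0.10, Stat2 at -0.11 and Ifit2 at -0.09 (adjusted p = 0.367, 0.420 and 0.453). The circadian clock genes had an adjusted p of 0.267, with Per1 at -0.40, Cry1 at -0.12 and Nfil3 at -0.21 (adjusted p = 0.0954, 0.421 and 0.525). When adjusted over the list alone, 1 of the clock genes fell. Without flagellin 7, Per1 fell by 0.43. The cell cycle genes had an adjusted p of 0.122, with Mki67 at -0.28, Pcna at -0.15 and Tpx2 at 0.09 (adjusted p = 0.245, 0.287 and 0.327).

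**Figure D3:**
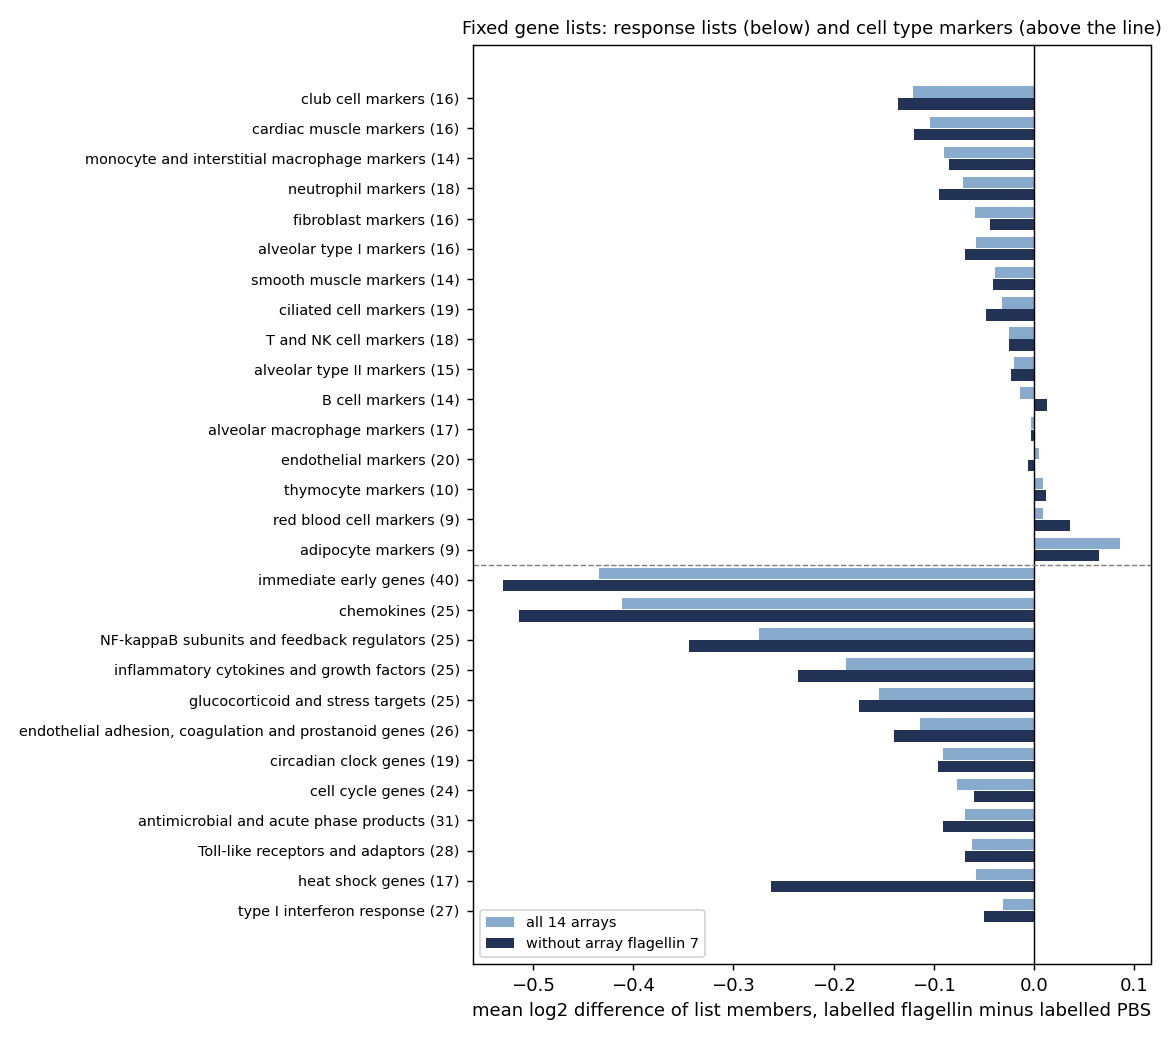
Mean log2 difference, arrays labelled flagellin minus arrays labelled PBS, of the measured members (number in brackets) of each fixed list, over all 14 arrays in light bars and without array flagellin 7 in dark bars. Immediate early genes had a mean of -0.43 over all 14 arrays and -0.53 without flagellin 7, chemokines -0.41 and -0.51, and heat shock genes -0.06 and -0.26.

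In the 16 cell type lists 0 marker genes passed over all genes tested with all 14 arrays, and camera called 4 lists. Club cell markers were lower (mean -0.12, adjusted p = 0.00606), with Bpifa1 and Muc5b the members of smallest p. With an estimated correlation the adjusted p was 0.601. Cardiac muscle markers were lower (mean -0.10, adjusted p = 0.0285), with Sln at -0.16 and Myoz2 at -0.14 (adjusted p = 0.439 and 0.508). With an estimated correlation that list had an adjusted p of 0.732. Alveolar type I markers were lower (mean -0.06, adjusted p = 0.0328), with Rtkn2 at -0.12 and Icam1 at -0.17 (adjusted p = 0.189 and 0.305), and an adjusted p of 0.525 with an estimated correlation. Without flagellin 7, Icam1, an adhesion molecule that NF-kappaB also induces, fell by 0.24. Adipocyte markers were higher (mean 0.09, adjusted p = 0.0328), with Retn at 0.13 and Car3 at 0.29 (adjusted p = 0.491 and 0.617), and an adjusted p of 0.612 with an estimated correlation. That call ended without flagellin 7 (adjusted p = 0.0884) and without any 1 of 5 other arrays, and the adjusted p ranged from 0.00492 to 0.612 over the alternatives.

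The other 12 cell type lists were not called. Neutrophil markers had a camera adjusted p of 0.506, with Clec4e at -0.36 (adjusted p = 0.263) and Mxd1 at -0.13 (adjusted p = 0.490). Without flagellin 7 Clec4e, an inducible receptor of myeloid cells, fell by 0.44. Monocyte and interstitial macrophage markers had an adjusted p of 0.0974 (C1qa -0.10, C1qc -0.07), alveolar macrophage markers 0.462 (Ctsd 0.10, Mrc1 -0.09) and alveolar type II markers 0.823 (Muc1 -0.06, Abca3 -0.07). Ciliated cell markers had an adjusted p of 0.267 (Cdhr3 -0.09, Tekt4 -0.08). Without flagellin 7 camera called them lower (adjusted p = 0.0265, with a range of 0.00596 to 0.936 over the alternatives), but with an estimated correlation the adjusted p was then 0.481. Endothelial markers had an adjusted p of 0.347 (Sox18 0.21, Gpihbp1 0.06) and fibroblast markers 0.198 (Col3a1 -0.18, Macf1 -0.09). Smooth muscle markers had an adjusted p of 0.198 (Smtn -0.13, Tagln -0.09), with 1 member lower when adjusted over the list alone. B cell markers had an adjusted p of 0.442 (Cd22 0.05, Blk 0.05), T and NK cell markers 0.954 (Eomes -0.10, Cd2 -0.08), thymocyte markers 0.198 (Dntt -0.06, Ptcra 0.07) and red blood cell markers 0.296 (Hba-a1 0.02, Klf1 0.02).

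Camera with its preset correlation called 11 of the 28 lists, and with an estimated correlation or with fry 0 were called (1 and 8 at an unadjusted p under 0.05). Without flagellin 7 camera called 12 lists. Of these, immediate early genes and chemokines were also called with an estimated correlation, and fry called 8 lists. RNA quality, read from the GAPDH control's 3-prime minus 5-prime signal, was -0.31 ± 0.04 in the arrays labelled flagellin and -0.33 ± 0.03 in those labelled PBS (n = 7 each, exact permutation p = 0.318). The beta-actin control stood at 0.47 ± 0.05 and 0.48 ± 0.03 (exact permutation p = 0.674). With the GAPDH difference as a covariate, 7 genes were lower and 0 higher over all 14 arrays.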

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

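The tests of explanations below were chosen after the results were seen, while leaving out each array in turn was planned. Each of 190 sets of 7 values, those of the named genes and the control differences in each group, was searched for an array that stands apart, by the gap to its neighbour as a share of the whole range, with 0.568 as the limit. It marked 40, and 34 of them were the array labelled flagellin 7. Chance alone would mark about 5% of sets chosen without sight of their values. That rate does not apply to the 23 genes chosen after their values were seen, which gave 17 of the 34 marks. The genes of the rule and the controls, the former ranked on these same arrays, gave 21 marks in 144 sets, 17 of them flagellin 7.

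In that array the response genes marked stood above the other 6 arrays labelled flagellin. Not all response genes did, since Ccl17, Cebpd, Mt2 and Bpifa1 lay within the range of those 6, at 6.89, 9.80, 8.60 and 10.89. Of the marked genes below, Ccl20, Ccl3, Il1b, Csf2, Atf3, Junb, Irf1, Hspa1a, Hspa1b, Hsph1, the 3 GTPases and the 4 sex-linked genes were chosen after their values were seen. The share of the range was 0.81 for Cxcl1, 0.837 for Cxcl2, 0.936 for Ccl20, 0.685 for Ccl3, 0.792 for Tnf, 0.92 for Il1a, 0.632 for Il1b and 0.885 for Csf2. It was 0.869 for Nfkbiz, 0.909 for Tnfaip3, 0.614 for Nfkbia, 0.801 for Zfp36, 0.692 for Ier2, 0.731 for Atf3, 0.716 for Junb and 0.904 for Irf1. For Ptgs2 it was 0.822, for F3 0.739, for Icam1 0.731, for Tlr2 0.721 and for Lcn2 0.694. Heat shock genes stood high as well, with 0.934 for Dnajb1, 0.906 for Hspa1a, 0.911 for Hspa1b, 0.726 for Hsph1, 0.712 for Hspa8 and 0.597 for Hspb8. So did the interferon-inducible GTPases Igtp (0.801), Gbp6 (0.621) and Irgm2 (0.848). Of the sex-linked genes, Xist stood apart at 0.943, Eif2s3y at 0.942, Kdm5d at 0.88 and Uty at 0.924.

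In other arrays, 6 values stood apart. Tab2 did so in flagellin 4 (0.584), Eomes in flagellin 2 (0.668), Tnf in PBS 4 (0.594), Hspb8 in PBS 2 (0.723), Eif2s3y in PBS 2 (0.641) and Kdm5d in PBS 6 (0.584).

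The first pattern is the direction of the whole response, with innate response genes lower in the arrays labelled flagellin. An exchange of the group labels may be behind it for 13 of the arrays. All 7 arrays labelled PBS have a chemokine list mean above the highest of the 6 other arrays labelled flagellin, which an exchange needs and which an effect in the labelled direction would give too, so both cannot be told apart without a mark of identity that is independent of the response. Flagellin 7 does not separate them either, since it goes against the other 6 arrays of its group both under the labels as given and under a full exchange. RNA degradation differing between the groups was not settled by adding the GAPDH control difference to the model. With flagellin 7 left out, 205 of the 268 lower genes stayed called with it. Their median log2 difference was -0.23 with and without it. The 268 were picked on these same arrays, and the control differed by 0.02 between the full groups (exact permutation p = 0.318). The covariate could therefore take away little of a difference, whatever its cause. With flagellin 7 kept, 7 genes were lower with the covariate, against 44 without it. An effect of the treatment as labelled stays open, as untested.

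The second pattern is flagellin 7 at the level of the arrays labelled PBS, with a chemokine list mean of 8.22 against 7.90 to 8.19 there and 7.43 to 7.55 in the other 6. A swap with an array labelled PBS is argued against, since 0 arrays labelled PBS lie in the range of those 6. RNA degradation is argued against as well, since the GAPDH control difference of -0.295 lies between the -0.378 and -0.254 of the other 13 arrays. Xist in this array is 2.03 above the highest of the other 13 and the Y-linked genes are low, which is the profile of a female, so an animal that differs in sex may be the source. With 1 such animal, its sex, another origin, a wrong label, other handling and a right label beside 13 exchanged ones cannot be told apart.

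Other splits of the arrays were counted for each result, 100 of 1716 drawn with the real one included. For the genes called over all 14 arrays, 2 splits gave as many, the real one with 45 and another with 251, a share under 0.05. With 100 of 1716 splits drawn, that share is imprecise, and it says nothing on the cause of the difference. That other split sets flagellin 7 with 6 arrays labelled PBS, against PBS 6 and the 6 other arrays labelled flagellin. It moves both flagellin 7 and PBS 6, so its count cannot be put down to flagellin 7 alone. Leaving out PBS 6 alone also gave more lower genes, 81 against 44. For genes at least 2-fold changed it was 2 splits, the real one with 8 and the same other split with 17, with the same limits. Chance could not be excluded for the number of lists called, since 40 splits gave 11 or more, the highest other 20. Without flagellin 7, the real split gave 284 genes (highest other 1), 16 at least 2-fold changed (highest other 0) and 12 lists (highest other 19). That array was picked after its values were seen, and no other split had an array picked the same way, so these counts do not test chance.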

How the results depend on the processing

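The comparisons by Dbp set, the fits that leave out flagellin 7 together with another change, the estimated correlation in settings where a list reversed, and robust regression were added after seeing the data. Counts are given as genes higher, lower and at least 2-fold lower in the arrays labelled flagellin, against 1, 44 and 8 as reported, and 0 genes were at least 2-fold higher in every alternative. Adjusted p-values near the threshold and the spread that 1 array adds limit the counts over all 14 arrays. Signals near the low end of the range, such as those of the probe sets used for Tlr5 and Hba-a1, limit what can be seen with them. A low signal describes the probe set and need not describe the level of the gene.

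The replicate numbers did not pair the arrays, since same-numbered arrays had correlations of their deviations between -0.243 and 0.188 (across genes), and 1 of 7 arrays labelled PBS matched its own number best. With the replicate block the counts were 0, 4 and 0 (15 genes 2-fold lower at an unadjusted p under 0.05), and 11 lists. A second quantile normalisation gave 5 higher and 19 lower, averaging the probe sets 0, 12 and 2, array weights 10, 161 and 16, trended and robust variance 0, 5 and 0, and probe sets in place of genes 2, 85 and 13. Leaving out the dimmest 40% gave 0 higher, since B3gat1 was among the genes removed, and 7 lists. At an adjusted p of 0.01, below the smallest one, the counts were 0, 0 and 0. The GAPDH covariate gave 0, 7 and 1. There Cxcl1 went from -3.32 (SE 0.574) to -3.46 (SE 0.603, adjusted p = 0.0561), so its call ended with a larger SE and not with a smaller difference. With that covariate and flagellin 7 left out the counts were 10, 218 and 16. With an estimated correlation and with fry 0 lists were called. Beyond these, the cause was not tested.

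Leaving out each array in turn, the genes higher ranged from 0 to 16, lower from 6 to 268, 2-fold lower from 1 to 16 and lists from 7 to 12. The highest gene counts came without flagellin 7, and the next without PBS 6 (3, 81 and 10). The Dbp set as a block gave 6, 113 and 14, the arrays of high Dbp 5, 148 and 17, those of low Dbp 0, 0 and 0, with fewer arrays in both, and the block without flagellin 7 gave 27, 383 and 16. Robust regression, for which lists were not run, gave 47, 347 and 16.

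The heat shock list turned to lower without flagellin 7 (mean -0.262, the lowest with 1 array left out, and -0.0113 the highest), in the arrays of high Dbp (-0.211), with the Dbp block and without flagellin 7 (-0.255), and with the GAPDH covariate and without flagellin 7 (-0.273). With an estimated correlation the adjusted p was 0.121, 0.0793, 0.108 and 0.113 in these 4 settings, so none of these calls held with it. Fry was run in the first of these settings, without flagellin 7, and called the list lower there (fry adjusted p = 0.00534). In the arrays of high Dbp the neutrophil list turned to higher (0.130, adjusted p = 0.436 with an estimated correlation) and Hsph1, a gene chosen after its values were seen, to lower (-0.378). In those of low Dbp the cardiac list had a mean of -0.0104, with camera's direction turned upwards and no call. Apart from the leaving out of flagellin 7, the cause was not tested. Of 3528 values of single genes and lists under the alternatives, 3067 stayed on their side of the threshold, 274 lost the call, 180 gained it and 7 reversed. A value counts as reversed where either fit called it and the direction, for lists that of camera, differed. Among the 7 only the cardiac list was called as reported, and it was not called in the other fit, so no call became a call the other way. Among the 3067 were 107 that were called in neither fit and changed sign. The 14 called genes among the named all kept their calls under array weights, without flagellin 7, without PBS 6, with the Dbp block and under robust regression. Of the 14, 0 kept their calls under trended and robust variance and in the arrays of low Dbp, 2 with the replicate block and with the GAPDH covariate, 5 with probe sets averaged, and 2 to 4 without any 1 of the other 12 arrays.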

Other observations

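Values of some clock genes, Dbp first, parted the arrays in both labelled groups. The arrays PBS 1, 2 and 3 and flagellin 1, 4 and 6 had Dbp signals from 9.36 to 10.17, and the other 8 from 6.59 to 7.56. In the first 6 arrays Per3, a clock gene with a rhythm close to that of Dbp, ranged from 7.69 to 8.34, and in the other 8 from 6.88 to 7.27. Tef ranged from 9.19 to 9.64 and from 8.38 to 8.73, and Nr1d2 from 9.94 to 10.23 and from 8.62 to 9.49. Arntl, which peaks at the opposite time of day, ranged from 6.51 to 6.86 in the first 6 and from 7.55 to 8.02 in the other 8. Of the 19 measured clock genes, 8 had ranges that did not overlap between these 2 sets, Dbp among them, and 11 overlapped, such as Per1 (7.92 to 8.78 and 7.81 to 8.50) and Cry1 (6.19 to 6.68 and 6.35 to 6.62). Chance parts 6 given arrays from 8 in 2 of 3003 orders, a rate for sets made without sight of a clock gene, which these were not. Tef, Nr1d2, Arntl and Per3 were chosen after their values were seen. The labels give no time of sampling, and no explanation was tested.

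A second group of genes stood apart in 3 arrays. Igtp, Gbp6 and Irgm2, GTPases that interferon gamma induces, had signals of 9.38, 9.20 and 9.15 in PBS 6, of 9.68, 9.21 and 9.29 in PBS 7, and of 9.33, 8.89 and 9.02 in flagellin 7. In the other 11 arrays Igtp was at most 8.27, Gbp6 at most 8.28 and Irgm2 at most 8.26. These 3 genes, and Hspa1a and Hspa1b below, were chosen after their values were seen. The 3 arrays belong to both labelled groups. The heat shock gene Hspa1b was also highest in them, at 8.66, 9.48 and 11.67, and Hspa1a stood at 7.56, 7.96 and 9.99.

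Sex-linked genes gave 1 profile for 13 arrays and another for 1, in 4 genes chosen after their values were seen. Xist, the RNA that coats the inactive X chromosome, was 8.75 in flagellin 7 and between 6.51 and 6.72 in the other 13. Kdm5d and Uty, which lie on the Y chromosome, were 6.13 and 6.37 in flagellin 7. In the arrays labelled PBS they stood at 8.12 ± 0.08 and 7.49 ± 0.11 (SD, n = 7). Eif2s3y, on the Y chromosome too, was 8.84 ± 0.10 in those, and lower in flagellin 7 than in any other array. Across genes, flagellin 7 correlated with the other arrays labelled flagellin at 0.988 to 0.991 and with those labelled PBS at 0.992 to 0.994, and the 6 others among themselves at 0.995 to 0.997.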
